A study of Mus musculus with 4 samples.

How the data were processed

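RNA-seq was analysed from 4 libraries of sorted mouse EGFP+ cells, 2 from untreated recipients and 2 from recipients given 5-FU. By the labels cells were sorted again from each recipient and the replicates are biological, so each library is taken as 1 recipient. Marrow mononuclear cells had been prepared on Lymphoprep, and the libraries were made with the SMART-Seq Ultra Low Input kit and read as 75 bp single ends. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 2.0.13 and Bowtie2 2.2.3, handled with SAMtools 0.1.19 and summarised with Cuffnorm 2.2.1, and the deposited values are FPKM (fragment counts divided by transcript length and by mapped reads) scaled between libraries by that tool. The day number in the column headers of the 5-FU libraries differs from that in their file names, and the groups and times used here are those of the labels. Cuffnorm's library normalization setting and the gene annotation are not given in the sources used here. The values are not whole numbers, and their sums of 678222 to 762107 per library differ.

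Depth is not given in the sources used here. In genes with low values, the worth of 1 read relative to 5-FU recipient 2 was 1.307 and 1.257 in control recipients 1 and 2 and 1.07 in 5-FU recipient 1, so a read weighed most in the control libraries. From such genes and the reference lengths, the median implied number of reads was 6140000 and 4520000 in control recipients 1 and 2 and 7880000 and 8430000 in 5-FU recipients 1 and 2. These rest on 18 to 20 genes per library and are rough. Whole reads were not recovered for the tests. An exact 0 is given only as listed at 0.

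The FPKM were used as deposited, with 1 added before log2, for genes at 1 FPKM or more in at least 2 of the 4 libraries. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 5.62. An exact permutation test over the 3 ways to part 4 libraries into pairs cannot go below p = 0.333, so none was used. The replicate numbers 1 and 2 occur in both groups and pair nothing that the labels name, so the main model has the group alone. On that reading the p-values measure the spread between recipients. The labels do not say whether the donor cells came from a common pool.

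Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 38 lists with at least 5 tested members. Of 39 lists with 1000 different genes, 963 genes matched by symbol, 15 through reference synonyms and 22 not at all. The list of mitochondrially encoded genes had no match and was not tested. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list. Coordinates and biotypes come from a GRCm38.p6 table, the build that mm10 corresponds to. Figures were drawn with matplotlib 3.10.9.

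The test, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule takes the 8 changed genes with the largest fold change in each direction with a mean of at least 5 FPKM in the higher group, leaving out predicted genes and small nucleolar, micro and ribosomal RNAs. It adds the 4 members of smallest p in each list that passed, at most 2 in each other list, and Kit, Ly6a, Ptprc, Cd34, Flt3, Slamf1, Mki67, Cdkn1a, Myc and Csf1r. Rnu12, a spliceosomal RNA, is 1 of the 8 lower genes, with 52.8 and 16.9 FPKM in control libraries and listed at 0 in both 5-FU libraries. It is 150 bp long, and values of such short features can rest on few reads. Other genes that the rule takes are counted within their lists and not described singly, and a member of the S phase list is not reported here. All genes named outside the rule were chosen after their values were seen.

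The tests were tried on simulated data in which each gene took the mean spread of genes of like expression in these libraries. Genes of low expression were not among those changed in the gene runs. Simulated genes of like expression all had the same spread, whereas real ones differ in spread. The rates that follow belong to that simpler setting and may be better than those in these data. With 200 genes changed in each of 10 runs, limma called 24.3% of genes changed by 1 on the log2 scale, 95.4% by 2 and 100% by 3, and 0.132% of unchanged genes. A list raised by 0.5 was called in 10 of 10 runs, against 0 of 350 tests of other lists. Simulated genes were drawn independently, whereas the estimated correlation in the real lists reached 0.55 for G2/M and 0.96 for cytosolic ribosomal proteins. The list runs therefore say nothing about false calls from correlated members.

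The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, quantile, TPM and median-ratio scaling, robust eBayes, no trend, the replicate number as a block, and leaving out each library. Protein-coding genes only and genes above 0 in all 4 libraries were added after seeing the data. Tests for raw counts and for recovered reads were planned and not run, since the values are FPKM.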

Results

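RNA was sequenced from EGFP+ cells sorted from a recipient mouse 24 h after a transplant of hematopoietic stem and progenitor cells. The donor cells were LSK cells, the Lin− Sca1+ c-Kit+ fraction of bone marrow that holds stem and multipotent progenitor cells, from mice that express EGFP under the ubiquitous CAG promoter. Each wild-type recipient was given 100000 LSK cells. Control recipients were untreated, and the other group had been given 5-fluorouracil (5-FU) at 200 mg/kg 2 days before the transplant. 5-FU is a pyrimidine analog that blocks thymidylate synthesis and kills dividing cells. EGFP+ cells were sorted again from the marrow of each recipient, and there were 2 libraries per group, 4 in all. The comparison asks how the transcripts of EGFP+ cells recovered from a 5-FU-conditioned marrow differ from those of EGFP+ cells recovered from an unperturbed marrow. Macrophage transcripts were abundant in every library, so a difference need not lie within progenitors.

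The deposited FPKM cover 23284 gene symbols. Between 14062 and 14395 genes had a value above 0 in a library. The FPKM of a library summed to 680412 and 678222 in the control recipients and to 678270 and 762107 in the 5-FU recipients. Across the tested genes the log2 values correlated at r = 0.969 within the control pair and 0.956 within the 5-FU pair, and at 0.896 to 0.929 between groups (correlations across genes, which are not independent replicates).

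Cells from 5-FU-treated recipients had higher transcripts of growth and division and lower transcripts of the erythroid, granulocyte and B lineages, of macrophages and of the immediate early response. These are list calls at a preset inter-gene correlation, and none held with an estimated correlation (smallest adjusted p = 0.39). With an estimated correlation the test also has only the 2 residual degrees of freedom, so few lists could pass. G2/M genes were raised by a median of 1.70 on the log2 scale and ribosome biogenesis genes by 1.44. Ngp, which encodes a secondary granule protein of neutrophils, went from 1410 ± 169.7 to 80.1 ± 6.17 FPKM (mean ± SD, n = 2 and 2), and Cdkn1a, the cell cycle inhibitor p21, from 4.10 ± 1.01 to 71.7 ± 10.6. Stem cell program genes had a list median of −0.20, which was −0.03 without 5-FU replicate 1 and −0.36, and then past the threshold, without 5-FU replicate 2 (adjusted p = 0.039). Of 11496 genes tested, 946 were higher and 537 lower at an adjusted p under 0.05 in limma-trend, so 63.8% of the 1483 changed genes were higher. The change was at least 2-fold for 734 of the higher and 409 of the lower genes. Without any variance model, 396 genes were at least 2-fold higher, and 200 at least 2-fold lower, in both 5-FU libraries than in both control libraries. The other 2 ways to part the 4 libraries into pairs gave 12 and 29 such genes, and 4 and 3 genes past the limma-trend threshold. Each of those ways mixes control and 5-FU libraries on both sides. A group difference then adds to the spread within the sides, so these low numbers are not a null level. The counts depended on the fit: 548 higher and 299 lower without a mean-variance trend, and 3 and 4 with no filter on low values, where the unadjusted p was under 0.05 for 3680 genes against 3607 in the filtered set. Leaving out control replicate 1 or 2 left 88 or 92 higher and 38 or 43 lower genes, and leaving out 5-FU replicate 1 raised them to 2122 and 1876, with the lone library assumed to vary like the other group.

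**Figure D1:**
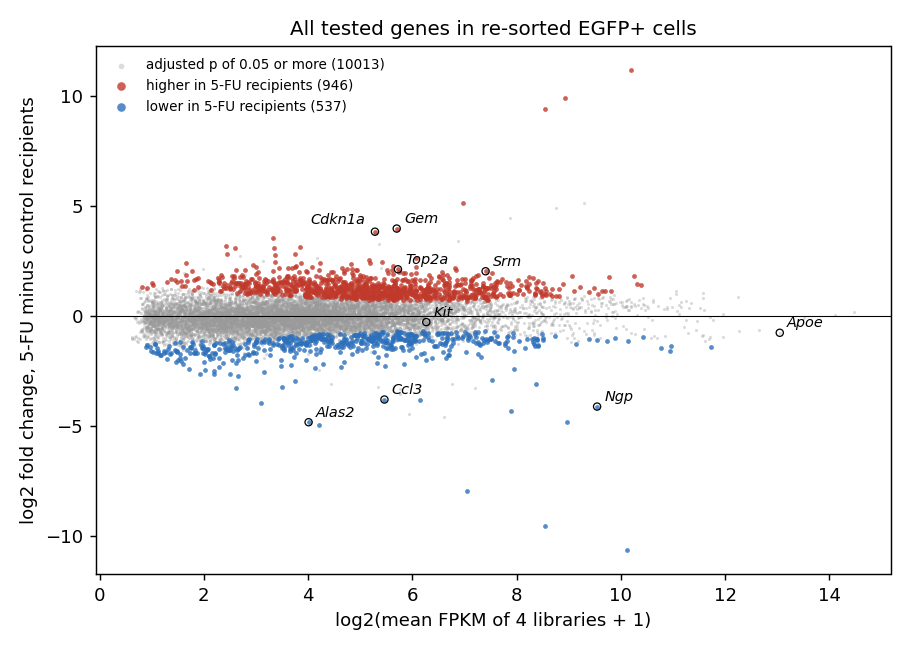
Each point is 1 of 11496 tested genes, at log2 of its mean FPKM plus 1 over the 4 libraries and its log2 fold change between 5-FU and control recipients; red and blue points are the 946 higher and 537 lower genes. Cdkn1a and Gem stand at the upper edge of the annotated genes and Alas2 and Ngp at the lower edge, while Kit lies near 0; the red and blue points farthest from 0 are small RNA features.

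Genes of mitosis and of DNA replication rose together. In the G2/M list 39 of 42 tested members rose, none fell and 3 did not pass, and 41 rose when adjusted over the list alone (camera adjusted p = 1.6e-24). That call has an adjusted p = 0.41 with an estimated correlation. Top2a, which untangles DNA in mitosis, had 18.6 ± 1.40 FPKM in control and 85.1 ± 9.53 in 5-FU recipients, a log2 fold change of 2.13 (SE 0.20, adjusted p = 0.0043). Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 39.4 ± 8.66 to 184.2 ± 21.5 FPKM. Ccnb1, the mitotic cyclin B1, went from 12.3 ± 3.90 to 71.7 ± 21.8, Birc5 (survivin) from 26.4 ± 0.934 to 106.4 ± 24.7 and Mki67, the Ki-67 proliferation antigen, from 9.09 ± 0.632 to 31.5 ± 7.10. In the S phase list 25 of 40 rose and 15 did not pass, 36 rose when adjusted over the list alone. The median was 1.21 (camera adjusted p = 2.9e-17, and adjusted p = 0.41 with an estimated correlation). All 40 members had a positive fold change. The helicase cofactor gene Cdc45 rose by 2.44 (SE 0.28), Uhrf1, which maintains DNA methylation, by 1.98 (SE 0.24) and the flap endonuclease gene Fen1 by 1.58 (SE 0.20). Between the same groups the macrophage list moved the other way, with a median of −0.91, and so did the list of dissociation and handling genes, at −0.98.

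Genes of ribosome biogenesis and of one-carbon and nucleotide metabolism rose as well. Of 44 members of the list of MYC targets and ribosome biogenesis, 41 rose, none fell and 3 did not pass, and 42 rose when adjusted over the list alone (camera adjusted p = 1.6e-24, and adjusted p = 0.39 with an estimated correlation). Srm, spermidine synthase, went from 65.2 ± 5.09 to 271.7 ± 32.3 FPKM, a log2 fold change of 2.04 (SE 0.20, adjusted p = 0.0044). The ribosome assembly genes Mrto4 and Nop58 rose by 1.72 and 1.71, and the mitochondrial chaperonin gene Hspd1 by 1.54. Myc itself went from 64.3 ± 2.71 to 175.2 ± 55.7 FPKM (log2 fold change 1.40, SE 0.25, adjusted p = 0.017). For thymidylate and deoxynucleotide synthesis, the pathway that 5-FU blocks, 18 of 23 members rose, 1 fell and 4 did not pass, with 20 and 1 when adjusted over the list alone and a median of 1.39 (camera adjusted p = 8.2e-11, and adjusted p = 0.41 with an estimated correlation). The folate enzyme genes Shmt1, Mthfd2 and Mthfd1 rose by 2.41, 2.14 and 1.58, and the nucleoside diphosphate kinase gene Nme1 by 1.62. Tyms, the target of 5-FU, was 1.96 higher, and the member that fell was Upp1, uridine phosphorylase, at −1.51; both were picked out after their values were seen.

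Protein turnover and energy metabolism shifted by smaller amounts. The proteasome list had a median of 0.65, with 6 of 31 members past the threshold, 23 when adjusted over the list alone, and all 31 positive (camera adjusted p = 4.4e-09, and adjusted p = 0.41 with an estimated correlation); Psmb5, a catalytic subunit, went from 116.6 ± 2.98 to 260.7 ± 56.8 FPKM. Among heat shock genes 8 of 15 rose and 7 did not pass, 10 rose and 1 fell when adjusted over the list alone. The median was 0.87 (camera adjusted p = 2.4e-05, and adjusted p = 0.41 with an estimated correlation), with Hsph1 at 1.88, Hspe1 at 1.62 and Hsp90aa1 at 1.52. Of 53 nuclear genes of oxidative phosphorylation 8 rose and 45 did not pass, likewise 8 when adjusted over the list alone, and 52 were positive with a median of 0.45 (camera adjusted p = 3.1e-08, and adjusted p = 0.60 with an estimated correlation). Cycs, cytochrome c, went from 54.4 ± 0.442 to 151.1 ± 40.6 FPKM. Glycolysis genes had a median of 0.51, with 6 of 21 past the threshold and 15 not, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.41 with an estimated correlation). Ldha, lactate dehydrogenase A, rose by 1.47 (SE 0.21) and Pgk1, phosphoglycerate kinase, by 1.46 (SE 0.20). All 48 cytosolic ribosomal protein genes were positive with a median of 0.52, which was 0.83 without 5-FU replicate 1 and 0.26 without 5-FU replicate 2, but only Rpl30 and Rpl5 passed singly and 0 when adjusted over the list alone (camera adjusted p = 7.4e-07, and adjusted p = 0.63 with an estimated correlation). Rps2 had 1332 ± 89.1 and 2951 ± 709 FPKM, and its adjusted p of 0.054 did not pass.

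**Figure D2:**
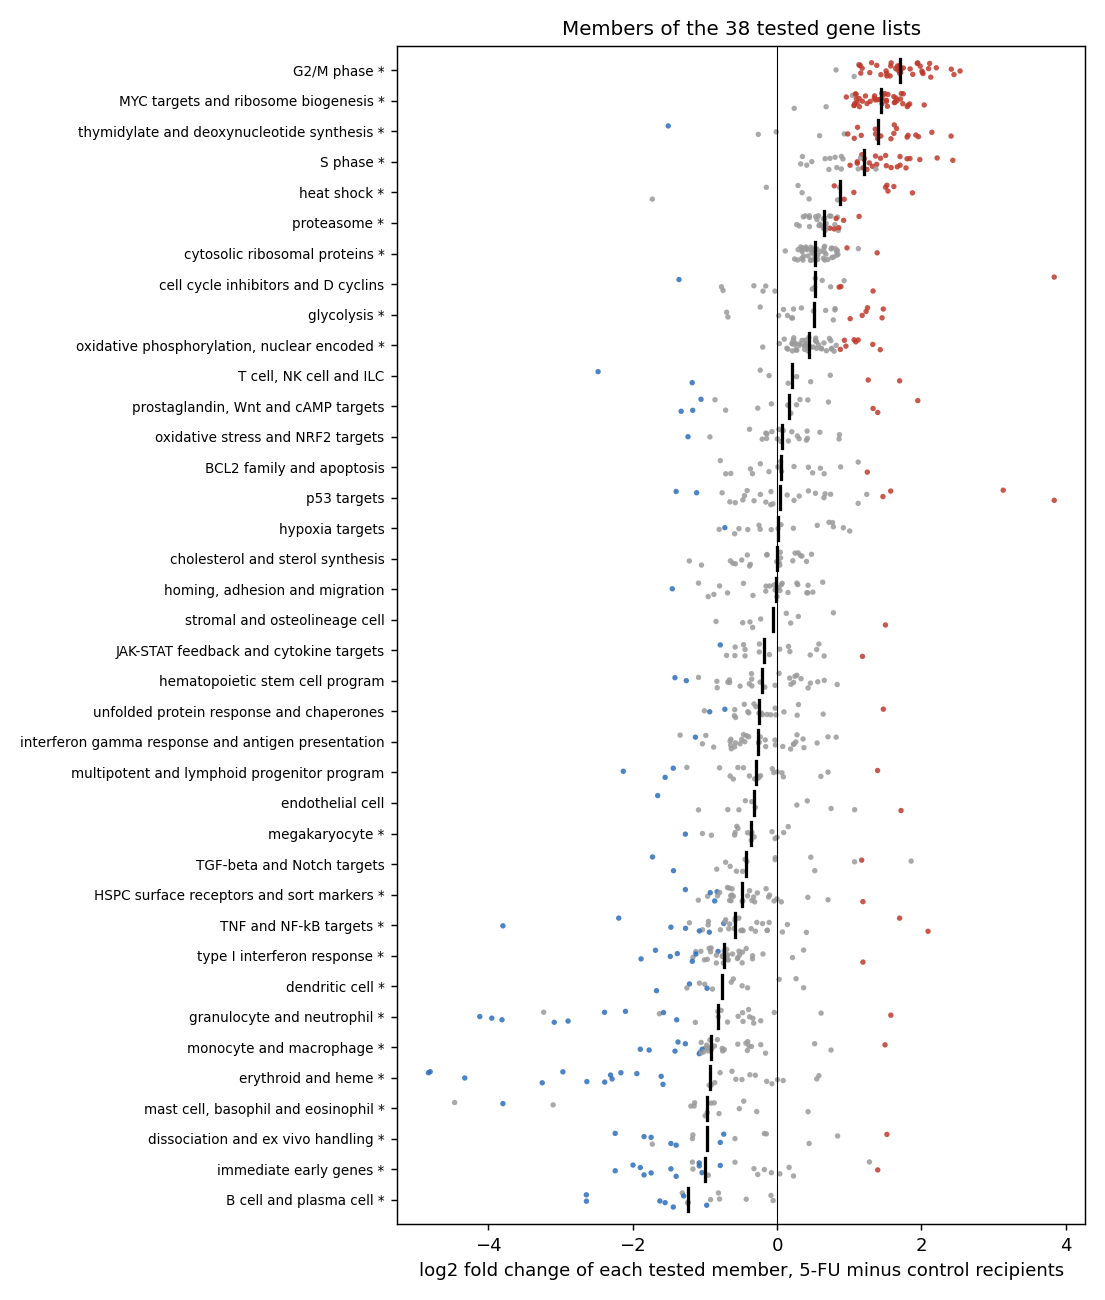
Each row is 1 of the 38 tested gene lists, ordered by its median (black bar), and each point is a member's log2 fold change, red where it rose, blue where it fell and grey where its adjusted p did not pass; an asterisk marks the 21 lists past the camera threshold. The G2/M list has the highest median, 1.70, and the B cell and plasma cell list the lowest, −1.23, which was −0.76 without 5-FU replicate 2.

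Of the 38 lists, 9 were higher and 12 lower by camera with its preset inter-gene correlation. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.39 and 3 lists had an unadjusted p under 0.05. That form of camera uses the 2 residual degrees of freedom, which raises p whatever the correlation. For the granulocyte list the estimate, 0.0071, was below the preset 0.01. Its unadjusted camera p still went from 5.5e-09 to 0.027. Loss of a call therefore does not show that inter-gene correlation accounts for it. By fry, which asks whether a list moves 1 way on balance, 6 lists passed: ribosome biogenesis and glycolysis higher, and the erythroid, granulocyte, HSPC surface and handling lists lower.

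The strongest single rises included genes induced by p53. Cdkn1a, on chromosome 17 at 29090979 to 29100722 (coordinates here are GRCm38.p6), rose by 3.84 (SE 0.25, adjusted p = 0.00057). Phlda3, a p53-induced inhibitor of AKT signalling on chromosome 1 at 135766085 to 135769134, rose by 3.13 (SE 0.42, adjusted p = 0.011). The p53 list as a whole did not move to either side, with a median of 0.04, 4 of 28 members up, 2 down and 22 not past, and 5 and 3 when adjusted over the list alone (camera adjusted p = 0.45). Besides Cdkn1a and Phlda3 the members that rose were Aen, an apoptosis-enhancing nuclease, at 1.47 and the mitotic gene Gtse1 at 1.57, and those that fell were Btg2 at −1.40 and Sesn1 at −1.11, the last 4 picked out after their values were seen. Gem, a small GTPase gene on chromosome 4 at 11704447 to 11714993, had the largest fold change of the higher named genes, from 4.89 ± 0.354 to 97.0 ± 43.2 FPKM (log2 fold change 3.98, SE 0.31, adjusted p = 0.0019). Ankle1, an endonuclease gene on chromosome 8 at 71405986 to 71410728, went from 2.34 ± 0.639 to 22.7 ± 0.00905 FPKM (adjusted p = 0.0044). The remaining 4 genes of the 8 with the largest rise are best known from epithelia or the acute phase and were uneven between the 5-FU libraries. Tff3, a goblet cell trefoil peptide, was listed at 0 in both control libraries and had 32.8 and 3.19 FPKM in 5-FU recipients 1 and 2, and the goblet cell lectin gene Zg16 had 1.22 and 0.293 against 28.9 and 6.05. Without 5-FU replicate 1 the log2 fold change of Zg16 went from 3.10 to 2.06. The serum amyloid gene Saa1 was listed at 0 in control 1 and had 0.314 FPKM in control 2 against 14.2 and 3.25, and the intestinal cadherin gene Cdh17 had 0.0400 and 0.154 against 4.52 and 15.4. Of the inhibitors and D cyclins, 4 of 17 rose, 1 fell and 12 did not pass, with 5 and 2 when adjusted over the list alone, a median of 0.52 and no list call (camera adjusted p = 0.099), though it passed without control replicate 1 (adjusted p = 0.025). Ccng2, a cyclin associated with cell cycle arrest, fell by 1.36, and the other 3 that rose were Ccnd1, Ccnd3 and E2f1, picked out after their values were seen.

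Transcripts that identify stem and progenitor cells were present in every library. Kit, the c-Kit receptor used for the donor sort, had 84.2 ± 26.3 FPKM in control and 67.8 ± 2.33 in 5-FU recipients (log2 fold change −0.27, SE 0.24, adjusted p = 0.49). Cd34 had 138.5 and 115.9 FPKM in control and 162.7 and 264.3 in 5-FU recipients (adjusted p = 0.11) and Flt3 had means of 85.3 ± 6.73 and 56.1 ± 10.7 (adjusted p = 0.095). Slamf1 stayed between 0.2 and 0.9 FPKM and was not tested. Ly6a, which encodes Sca1, rose from 17.8 ± 1.21 to 43.2 ± 15.2 FPKM (log2 fold change 1.19, SE 0.27, adjusted p = 0.032). In the list of HSPC surface receptors and sort markers Ly6a was the 1 member of 33 that rose, 4 fell and 28 did not pass, with 1 and 5 when adjusted over the list alone. The list median was −0.48 (camera adjusted p = 0.00029, and adjusted p = 0.39 with an estimated correlation). The members that fell were Csf1r, Ifngr1, Ptprc and Ifnar1, the last picked out after its value was seen. Macrophages express them as well. Csf1r, the M-CSF receptor, had 204.3 and 225.6 FPKM in control and 116.4 and 67.2 in 5-FU recipients 1 and 2, and Ptprc (CD45) went from 130.4 ± 0.506 to 73.1 ± 6.70. The stem cell program showed no list call at a median of −0.20, where none of 28 rose, Sult1a1 and Gimap6 fell and 26 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.29). Sult1a1 was at −1.41, and at −0.92 without 5-FU replicate 2. The stem cell median was −0.03 without 5-FU replicate 1, and without 5-FU replicate 2 it was −0.36 and the list passed as lower (adjusted p = 0.039). The multipotent and lymphoid program had a median of −0.29 with 1 of 22 up and 3 down, likewise 1 and 3 when adjusted over the list alone, and no list call (camera adjusted p = 0.068). That median was −0.09 without 5-FU replicate 1 (adjusted p = 0.55), and the list passed as lower without 5-FU replicate 2 at −0.52 (adjusted p = 0.0015) and without control replicate 2 at −0.36 (adjusted p = 0.013). Its lower members were the lymphoid genes Dntt, terminal transferase, at 63.4 ± 28.7 and 14.3 ± 8.67 FPKM, Blnk, and Ebf1, and the higher was Il12a; Ebf1 and Il12a were picked out after their values were seen.

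Erythroid, granulocyte and B lineage transcripts were lower. Alas2, the erythroid aminolevulinate synthase gene on chromosome X at 150547417 to 150570622, had 25.7 and 34.5 FPKM in control recipients. It was listed at 0 in 5-FU recipient 1 and had 0.173 in recipient 2. The globin genes Hba-a2 and Hbb-bs, listed in the files as Beta-s, went from 450.2 ± 138 to 21.9 ± 9.42 and from 958.9 ± 225 to 37.6 ± 26.2 FPKM; globin copies share reads, so the value of each copy is uncertain. Of 28 erythroid and heme genes 13 fell and 15 did not pass, 17 fell when adjusted over the list alone. The median was −0.92, or −0.91 without the 1 member listed at 0 in a whole group (camera adjusted p = 5.4e-09, and adjusted p = 0.39 with an estimated correlation). Among 27 granulocyte and neutrophil genes 9 fell, 1 rose and 17 did not pass, 11 fell and 1 rose when adjusted over the list alone. The median was −0.81, or −0.79 without 1 member listed at 0 in a whole group (camera adjusted p = 3.0e-08, and adjusted p = 0.39 with an estimated correlation). Ngp, on chromosome 9 at 110419808 to 110423012, fell by 4.12 (SE 0.21, adjusted p = 0.00016). The fold change was −3.09 (SE 0.27) for the antimicrobial peptide gene Camp and −2.89 (SE 0.20) for the lactoferrin gene Ltf. Chi3l3 (Chil3) fell by 3.81 (SE 0.35) and shares sequence with neighbouring chitinase-like copies, so its value is uncertain. Fcnb, a ficolin gene, had 10.5 and 19.8 FPKM in control libraries and was listed at 0 in both 5-FU libraries. The member that rose was Ctsg, cathepsin G, at 1.58, picked out after its value was seen. In the B cell and plasma cell list 7 of 16 fell, none rose and 9 did not pass, 8 fell when adjusted over the list alone. The median was −1.23 (camera adjusted p = 7.0e-06, and adjusted p = 0.41 with an estimated correlation). Cd79b, a B cell receptor component, fell from 320.3 ± 9.03 to 162.8 ± 11.6 FPKM, and the surrogate light chain gene Vpreb3 had 8.26 and 8.90 FPKM in control recipients 1 and 2, 1.35 in 5-FU recipient 1 and was listed at 0 in recipient 2. Igll1 had 3.54 and 7.57 FPKM in control libraries and was listed at 0 in both 5-FU libraries, and the list median without it was also −1.23. The B list median was −0.76 without 5-FU replicate 2, −1.83 without 5-FU replicate 1 and −0.59 with a pseudocount of 5. For the granulocyte list it was −1.32 without 5-FU replicate 1 and −0.54 without 5-FU replicate 2.

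Further lineage lists fell with fewer single genes. The mast cell, basophil and eosinophil list had a median of −0.97 (camera adjusted p = 0.0015, and adjusted p = 0.41 with an estimated correlation). Of its 15 members 1, Ccl3, passed the threshold, 14 did not, and 3 were lower when adjusted over the list alone. Ccl3 is also a member of the list of TNF and NF-kB targets, so it is not particular to this lineage. The dendritic cell list had a median of −0.76, with Naaa, Cd7 and Cst3 lower and 11 of 14 not past, likewise 3 when adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.39 with an estimated correlation). For megakaryocyte genes the median was −0.36, and Clec1b fell while 16 of 17 did not pass, with 1 when adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.60 with an estimated correlation). The megakaryocyte median was −0.13 and −0.69 without 5-FU replicate 1 and 2, and −0.15 and −0.59 without control replicate 1 and 2. That call ended without control replicate 1 (adjusted p = 0.21), without 5-FU replicate 1 (adjusted p = 0.21) and with a filter of 5 FPKM (adjusted p = 0.050). The mast cell, basophil and eosinophil median was −0.61 without 5-FU replicate 1, and the dendritic cell median −0.46 with a pseudocount of 5. Prss34, a basophil protease gene, had 238.6 and 1.24 FPKM in control recipients 1 and 2, was listed at 0 in 5-FU recipient 1 and had 0.0988 in recipient 2 (adjusted p = 0.13).

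Macrophage transcripts were among the most abundant in all 4 libraries, and they were lower in the 5-FU recipients. Over the 34 members of the monocyte and macrophage list, the median mean FPKM was 188.2, which is percentile 95.4 of the tested genes, and 22 members exceeded 100 FPKM. The stem cell program had a median of 6.56 FPKM, at percentile 31.8. Apoe had 9955 and 11157 FPKM in control recipients 1 and 2 and 7743 and 5005 in 5-FU recipients 1 and 2, and the complement gene C1qb had 4304 and 4587 against 2690 and 1718; both were picked out after their values were seen. The list median per library was 240.9 and 260.1 FPKM in control and 182.1 and 86.5 in 5-FU recipients 1 and 2. In the test 7 of 34 fell, 1 rose and 26 did not pass, 18 fell and 1 rose when adjusted over the list alone. The median fold change was −0.91 (camera adjusted p = 6.1e-07, and adjusted p = 0.60 with an estimated correlation). The median was −0.47 without 5-FU replicate 2 and −1.24 without 5-FU replicate 1. Timd4, the phosphatidylserine receptor TIM-4 of resident macrophages, went from 160.9 ± 22.2 to 46.8 ± 11.1 FPKM (log2 fold change −1.77, SE 0.23, adjusted p = 0.0098). Ms4a7 fell by 1.37 (SE 0.21), Cd14, the lipopolysaccharide co-receptor, by 1.41 (SE 0.29) and the transcription factor gene Klf4 by 1.89 (SE 0.29). Klf4 ran from −2.31 to −1.09 over the alternative settings. The member that rose was Ccr2, a chemokine receptor of inflammatory monocytes, from 4.27 ± 0.978 to 14.2 ± 4.94 FPKM, picked out after its value was seen.

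Immediate early, NF-kB and type I interferon genes were lower, between the same groups in which the macrophage list fell by a median of −0.91. Of 24 immediate early genes 11 fell, 1 rose and 12 did not pass, 13 fell and 1 rose when adjusted over the list alone. The median was −0.996 (camera adjusted p = 7.6e-06, and adjusted p = 0.39 with an estimated correlation). Fos went from 245.4 ± 1.81 to 69.5 ± 22.4 FPKM (log2 fold change −1.84, SE 0.25, adjusted p = 0.010) and Fosb fell by 2.24 and Klf2 by 2.00; the member that rose was Myc. The list of dissociation and ex vivo handling genes, which shares Fos, Fosb, Jun and other members with it, had 7 of 16 down, Hsp90aa1 up and 8 not past, 10 and 2 when adjusted over the list alone, and a median of −0.98 (camera adjusted p = 0.00055, and adjusted p = 0.39 with an estimated correlation). Among 35 TNF and NF-kB targets 7 fell, 2 rose and 26 did not pass, 10 and 2 when adjusted over the list alone, with a median of −0.58 (camera adjusted p = 7.9e-06, and adjusted p = 0.39 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 went from 81.4 ± 7.03 to 4.94 ± 0.765 and from 92.2 ± 9.71 to 19.6 ± 4.70 FPKM; their reference intervals on chromosome 11 overlap, so reads in the overlap cannot be assigned with certainty. Zfp36, which destabilizes cytokine mRNA, fell by 1.47 (SE 0.20). The members that rose were Ccl5, by 1.70 (SE 0.23), and Cd69, at 2.09 and picked out after its value was seen. In the type I interferon list 7 of 41 fell, 1 rose and 33 did not pass, 16 fell and 1 rose when adjusted over the list alone, and 38 were negative with a median of −0.73 (camera adjusted p = 3.1e-08, and adjusted p = 0.41 with an estimated correlation). Isg20 fell by 1.88 (SE 0.30), Ifi44 by 1.48 and Parp14 by 1.12. Over the alternative settings Ifi44 ran from −1.80 to −0.85. The member that rose was Ly6a, which is also the Sca1 sort marker.

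**Figure D3:**
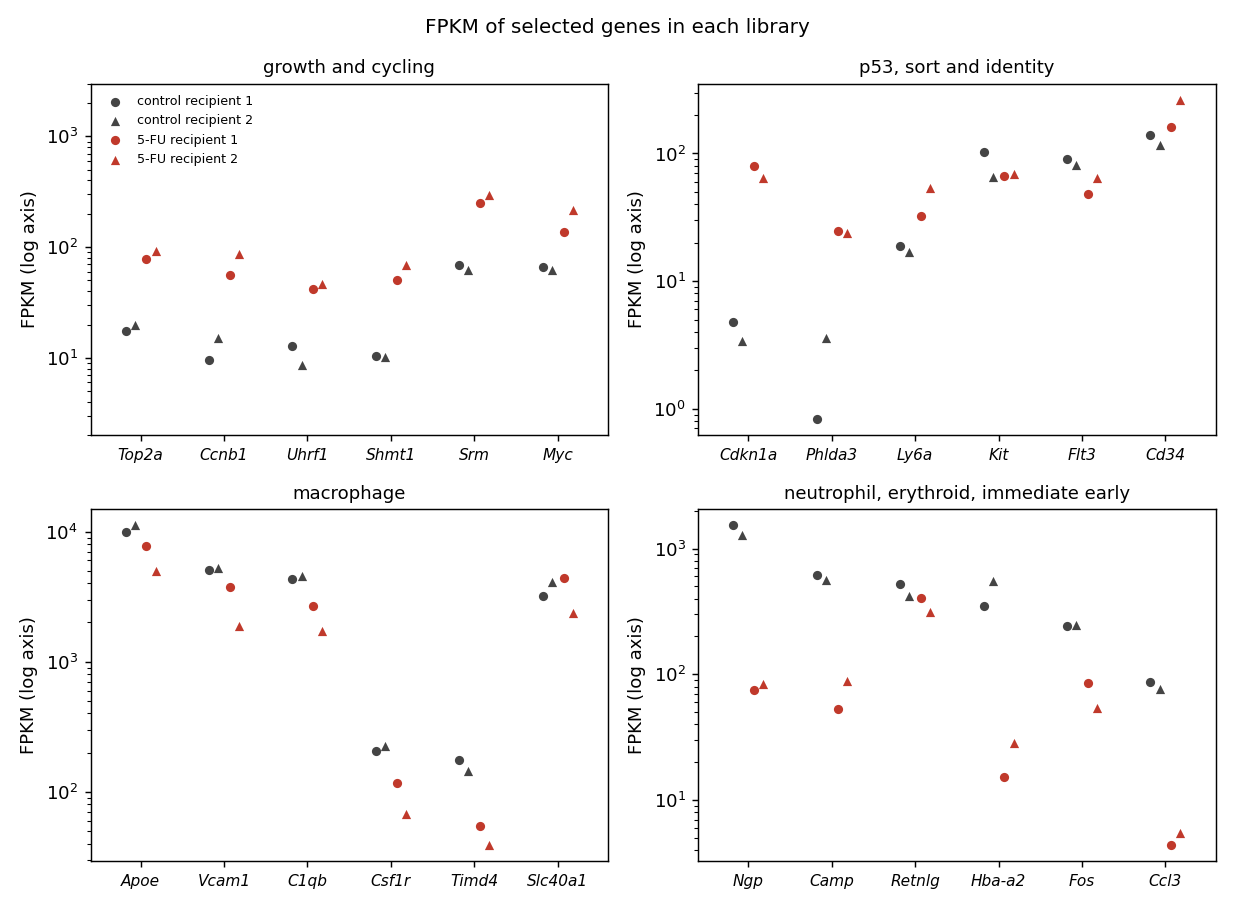
Points are the FPKM of 24 genes in each library on a log axis, grey for control and red for 5-FU recipients, circles for replicate 1 and triangles for replicate 2. Ngp falls from above 1290 FPKM in both control libraries to below 84.5 in both 5-FU libraries, whereas Retnlg, a neutrophil gene picked out after its values were seen, lies between 313.6 and 523.7 and Kit between 65.5 and 102.8.

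Besides the stem cell, multipotent, p53 and inhibitor lists described above, 13 tested lists did not pass the camera threshold. Interferon gamma and antigen presentation genes had a median of −0.26 (adjusted p = 0.068), with none of 35 up and Cd74, the MHC class II invariant chain, lower by −1.13 (0 when adjusted over the list alone). Without 5-FU replicate 1 that list passed at a median of −0.39 (adjusted p = 0.010), and without 5-FU replicate 2 the median was −0.13 (adjusted p = 0.21). Unfolded protein response genes had a median of −0.25 (adjusted p = 0.073), with Asns up at 1.47, Dnajb9 down at −0.93 and Dnajc3 at −0.72, and 1 and 2 when adjusted over the list alone. TGF-beta and Notch targets were at −0.43 (adjusted p = 0.45) with the Notch targets Hey1 and Hes1 down at −1.73 and −1.43 and Gfi1b up at 1.17, and 3 up and 3 down when adjusted over the list alone. Hey1, at 0.343 ± 0.345 FPKM in 5-FU recipients, ran from −3.22 to −0.66 over the alternative settings. Endothelial genes were at −0.33 (adjusted p = 0.67), with Egfl7 up at 1.72 and Stab2 down at −1.65 (−1.08 without 5-FU replicate 2), likewise 1 and 1 when adjusted over the list alone. For JAK-STAT feedback genes the median was −0.18 (adjusted p = 0.67), with Cish up at 1.18 and Junb down at −0.79, again 1 and 1 when adjusted over the list alone. Prostaglandin, Wnt and cAMP targets had a median of 0.17 (adjusted p = 0.85) with Birc5, Myc and Ccnd1 up and Hpgd, Ptgs1 and Ptger4 down, and 3 and 4 when adjusted over the list alone. T, NK and innate lymphoid genes had a median of 0.21 (adjusted p = 0.73), with Ccl5 and Nkg7 up and Klrd1 and Cd4 down, likewise 2 and 2 when adjusted over the list alone. Dnajc3, Gfi1b, Hpgd, Ptgs1, Ptger4, Nkg7 and Cd4 were picked out after their values were seen.

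The remaining 6 lists had medians near 0. They were homing and adhesion genes at −0.01 (adjusted p = 0.40, Rgs2 down at −1.45), NRF2 targets at 0.07 (adjusted p = 0.67, Txnip down at −1.23) and BCL2 family genes at 0.05 (adjusted p = 0.67, Bcl2 up at 1.25). Hypoxia targets were at 0.01 (adjusted p = 0.92, Bnip3l down at −0.72), with the camera direction lower, the mean at 0.08 and the median above 0. Cholesterol synthesis genes were at −0.00 (adjusted p = 0.48, none past), and stromal genes at −0.05 with a mean of 0.06 (adjusted p = 0.92), where Spp1, osteopontin, rose from 2.32 ± 0.205 to 8.43 ± 1.01 FPKM. When adjusted over the list alone, 1 homing gene fell, 1 stromal gene rose and 1 fell, and 0 members of the other 4 lists passed. The medians of these 6 lists and of the p53, JAK-STAT, TGF-beta and Notch, prostaglandin and T cell lists took the other sign in at least 1 alternative setting.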

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

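The settings that used protein-coding genes only and genes above 0 in all 4 libraries were chosen after the results were seen. No called gene changed sign in any setting. With no filter 16391 genes were tested, 3 were higher and 4 lower, and the prior degrees of freedom fell to 2.59, while the unadjusted p was under 0.05 for 3680 genes. Without a trend 548 were higher and 299 lower; the cause was not tested. Leaving out 1 library gave 88 to 2122 higher and 38 to 1876 lower genes: 88 and 38 without control replicate 1, 92 and 43 without control replicate 2, 2122 and 1876 without 5-FU replicate 1, and 1044 and 765 without 5-FU replicate 2. The lone library was assumed to vary like the other group. Of the 946 higher and 537 lower genes, 82 and 34 kept their call without control replicate 1, 87 and 41 without control replicate 2, 937 and 534 without 5-FU replicate 1, 854 and 497 without 5-FU replicate 2, and 791 and 426 with the replicate block. The replicate number as a block gave 855 higher and 539 lower genes and 9 higher and 13 lower lists; replicate differences of the groups correlated at r = −0.159 across genes, which are not independent. The other settings gave 776 to 1079 higher and 438 to 646 lower genes. Genes apart by 2-fold in every library, 596 in all, came to 263 with a pseudocount of 5, which shrinks folds of low values, and to 853 to 1938 without 1 library, where fewer libraries have to separate. TPM scaling moved the median of all genes to −0.09.

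Camera with an estimated inter-gene correlation called 0 lists higher and 0 lower, and fry called 2 higher and 4 lower. The 9 higher lists kept their call in all other settings, and so did the lower lists except the megakaryocyte list, with adjusted p from 0.050 to 0.21 where it was lost. The multipotent list was lower with quantile scaling (adjusted p = 0.036), with the block (0.044), without control replicate 2 (0.013) and without 5-FU replicate 2 (0.0015). The interferon gamma list passed with a filter of 5 FPKM, with quantile scaling and without 5-FU replicate 1, and the unfolded protein list with quantile and TPM scaling. The stem cell list passed as lower without 5-FU replicate 2 (adjusted p = 0.039), and the inhibitor list as higher without control replicate 1 (adjusted p = 0.025). Of 100 called named genes, 98 lost their call with no filter, 28 without a trend, 67 without control replicate 1 and 64 without control replicate 2; Ccl3 and Ngp kept it in every setting. Tff3 lost its call in 6 of the 14 alternative settings that tested it, among them a pseudocount of 5 (adjusted p = 0.073). Transcripts near 1 FPKM rest on few reads, and short RNA features can do so at much higher FPKM.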

Other observations

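All tests of explanations in this part were chosen after the results were seen, and so were the members left out of the neutrophil test and the bound of 0.1 used for the macrophage list.

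Some transcripts were high in a single library. The eosinophil gene Prg2 had 394.0 FPKM in control recipient 2 and 12.2 in control recipient 1, against 21.0 and 2.21 in 5-FU recipients 1 and 2, and the neutrophil elastase gene Elane had 147.7 in control recipient 2 and 1.82 to 4.94 in the others. The basophil protease gene Mcpt8 had 149.6 FPKM in control recipient 1, 2.58 in control recipient 2 and 5.92 and 15.02 in 5-FU recipients 1 and 2. Among intestinal epithelial genes looked up after the values of Tff3 were seen, Spink4 and Guca2a were listed at 0 in both control libraries and had 20.7 and 5.45 FPKM in 5-FU recipient 1 and 1.08 and 1.70 in recipient 2. In 5-FU recipients 1 and 2, Phgr1 had 9.90 and 1.49 FPKM, Epcam 2.53 and 1.45 and Krt8 3.14 and 1.31, each at most 0.549 in control libraries. Agr2 had 0.943 FPKM in control recipient 1, was listed at 0 in control recipient 2 and had 1.93 and 0.361 in 5-FU recipients 1 and 2. Fcgbp had at most 0.221 in any library, and Cdh17 was higher in 5-FU recipient 2.

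Gem and Cdh17, both among the 8 named genes of largest rise, are neighbours on chromosome 4 with a gap of 43.2 kb in GRCm38.p6. Of 10000 random draws of 8 protein-coding genes from 7838, 56 (0.56%) held a pair within 50 kb. The comparison and its window, slightly wider than the gap, were set after the pair was noticed, so the share is not a chance level. On the far sides, Rad54b rose (adjusted p = 0.023), to 5.85 and 7.70 FPKM in 5-FU recipients 1 and 2, and Pdp1 did not pass (adjusted p = 0.17). Of the called genes, 12 were small RNA features, 9 of them listed at 0 in a whole group. Snord33 had 2435 and 2276 FPKM in the 5-FU libraries, a ratio of 1.07, which equals the relative worth of 1 read there.

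The higher transcripts of the cell cycle, MYC target and nucleotide synthesis lists are the first pattern weighed. If a smaller share of macrophage RNA had raised all other transcripts alike, the stem cell and multipotent lists would have risen as much. The 145 members had a median of 1.44 and the 50 progenitor members −0.26, a difference of 1.70, which argues against it. The 95% bootstrap interval of 1.43 to 1.89 resampled list members, which are not independent. Recipients were not resampled, so the interval does not measure the spread between them. Scaling between the libraries is argued against by the lowest of the 4 list medians under 3 rescalings, 1.15, above the largest difference of a list mean between replicates, 0.404. Entry of the transplanted cells into cycle may account for the pattern, as a hypothesis, while recipient cells within the sort, or another mix of donor progeny, stay open and were not tested, since no transcript here separates donor from recipient.

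The second pattern is the fall of the macrophage list, whose members reach 11157 FPKM (Apoe in control recipient 2), although lineage-positive cells were removed from the donor cells before transplant and the EGFP sort excludes cells of wild-type recipients as far as it is pure. A smaller share of macrophage RNA of unchanged makeup may account for it. In limma on list-centred values, 0 of 31 members departed from the common change of −0.77 at an adjusted p under 0.05, but 7 were under 0.1 and the smallest was 0.056, so this and a change within macrophages cannot be told apart. The largest departures were above the common change, 1.52 for Marco (adjusted p = 0.056) and 1.29 for F13a1 (adjusted p = 0.092), both picked out after their values were seen. Whether this RNA came from recipient macrophages, from EGFP+ cells that took it up or from donor cells that matured was not tested.

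The third pattern is the fall of the granulocyte and neutrophil list. A smaller share of neutrophil RNA of unchanged makeup would move all members alike if no other cells held their transcripts. In limma on list-centred values, 10 of 14 members departed from the common change of −1.75, 4 lower and 6 higher. That test left out Mpo, Prtn3, Elane, Ctsg and Lyz2, which other marrow cells express. With none left out, the common change was −1.42 and 5 of 19 departed, 4 lower and 1 higher. The higher departures thus depended on which genes were left out. With those genes left out, Ngp departed by −2.37 and Retnlg, a gene of mature neutrophils, by 1.36. Of the primary granule genes, Mpo, Prtn3 and Elane did not pass (log2 fold changes −0.04, −0.48 and −3.23, adjusted p = 0.93, 0.18 and 0.12), with the Elane value resting on control recipient 2, and Ctsg rose. A source in other cells for the members that fell least stays open and would give departures as well. The test therefore cannot tell a smaller share of neutrophil RNA from a changed makeup, and no biological explanation was tested.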
